A study of Mus musculus with 16 samples.

How the data were processed

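Messenger RNA of the quadriceps of 16 C57BL/6 mice aged 6 months was sequenced on an Illumina NextSeq from stranded poly(A)-selected libraries, as paired-end reads, per the labels. The mice fall into 4 groups of 4: wild-type (WT) females, WT males, transgenic (Tg) females and Tg males. Littermates served as controls where possible, but no label links a transgenic mouse to its littermate and the replicate numbers only follow the order of deposition. No paired analysis was possible because of this. The labels name no sequencing batch or date.

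The labels give no unit for the values deposited by the authors. They were taken as estimated counts (expected_counts) of reads or fragments per gene symbol, since they are never negative, partly fractional and sum to a different total in each library. Per the labels the authors ran cutadapt and TopHat2 before these estimated counts were made, and the values are not scaled to a common total; they are given for 19108 gene symbols in every library. The submitters' processing notes name bcl2fastq, cutadapt 1.2.1, TopHat2, Bowtie2 and the mouse genome build mm10. The program that assigned reads to genes, its annotation and any filter on genes are not given in the sources used here. Of the nonzero values, 95.02% lie within 0.01, or within 1e-05 of their own size, of a whole number. The 25 values of at least 1000000, which belong to 2 genes (Myh4 and Atp2a1), are deposited with 3 significant digits. All values were rounded to whole numbers before the tests, which moved none by more than 0.5 and left 8 genes at 0 in all 16 libraries. No transcript encoded by mitochondrial DNA is listed, so these were not analysed here.

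Total counts, in units of 1000000, were 17.4 to 30.7 per library, with group medians of 19.9 in WT females, 24.9 in Tg females, 23.96 in WT males and 24.2 in Tg males. A count of 0 in a single library allows up to 3 counts, which is 0.101 to 0.165 counts per 1000000 (CPM). Intervals on ratios of counts have a 95% level and, like these limits, cover counting error only, since reads carried no molecular identifiers. CPM values were computed on library sizes scaled by trimmed mean of M-values (TMM) factors, which ranged from 0.887 to 1.10.

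Gene positions are those of the GENCODE M21 annotation of the same build; 18755 symbols (98.15%) matched 1 gene, 32 matched several and 321 matched none. The sex labels were checked against Xist and the Y-linked genes, and all 16 libraries matched. Among the 24 pairs of libraries within a group, the correlation of log2 CPM across genes was 0.955 to 0.992. Their lowest median chi-square per gene was 1.37 against 0.455 for repeated sequencing of 1 library, so no pair looked like the same library deposited again.

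Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed by filterByExpr (minimum count 10, minimum total 15), which left 13666 genes. A model with 1 mean per group was fitted to all 16 libraries with robust quasi-likelihood dispersion, and 6 contrasts were tested with the quasi-likelihood F test. These were the Tg minus WT difference averaged over the sexes, the same in females and in males, the male minus the female genotype effect (the interaction), and the male minus female difference in WT and in Tg. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 0.201. The standard error (SE) of a log2 fold change was its size divided by the square root of F. Adjusted p values below come from edgeR unless another tool is named, and all tests are two-sided unless stated.

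The 50 gene lists were written before the data were examined, with 47 holding at least 3 tested genes. They were tested with camera (limma 3.58.1) against the other genes at a preset correlation between genes of 0.01, and adjusted over the 47 lists. The lists not tested were the adenine nucleotide translocases, with 2 tested genes, the lymphocyte and neutrophil markers, with 1, and the transcripts of mitochondrial DNA, with 0. Numbers of list genes called are given over all tested genes and adjusted over the list alone. Results of each list are given in the report.

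The genes to be named were also fixed by a rule before the data were examined. For the averaged effect, it takes the 14 largest increases and 10 largest decreases among called genes with a mean log2 CPM of at least 1, a symbol that is not of a predicted gene or clone, and every Tg library beyond every WT library of its sex in the same direction. For each list it takes up to 4 called members with the smallest adjusted p, of which the text prints a part (some genes that the rule takes are not reported here), and, where none was called, the member with the highest mean CPM. For the interaction it takes up to 6 genes per direction, with a mean log2 CPM of at least 0, and for each sex difference up to 5 genes per direction with a mean log2 CPM of at least 1. Ucp1, Scd1, Fasn and the genes named only in the part on other observations fall outside this rule and were chosen after their values were seen. Eif3c, Igf2 and H19, also named in that part, come under the rule. Where fewer than 10 counts stood behind the WT group of a gene, the ratio of summed counts is given in place of the fitted fold change.

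The alternatives chosen before the data were examined were RLE and upper-quartile normalization, DESeq2 1.42.0, limma-voom, no filter, a filter on CPM of at least 1 in 4 libraries, a run without the 10 most abundant genes and Slc25a4, 1 surrogate variable (sva 3.50.0), fits on 1 sex, models without the interaction or without sex, a minimum absolute log2 fold change of 1, and each library left out in turn. For lists they were an estimated correlation between genes, fry and ranks. Runs without the 4 libraries highest in adipocyte markers, or with the mean of these markers as a covariate, were added after the data were seen.

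The pipeline was tested on simulated counts with the depth and the spread per gene of these libraries, drawn independently for each gene. In the averaged effect, 22% of genes changed 1.25-fold were called in the right direction, 72% at 1.5-fold, 88% at 2-fold and 98% at 4-fold. For the interaction the shares were 0%, 6%, 64% and 78%, and for the sex difference in WT 0%, 36%, 66% and 92%. False calls made up 4.11%, 5.13% and 3.00% of all calls in these 3 comparisons. Variation that many genes share between libraries, such as that of adipose RNA, was not simulated, so these shares may not hold in the real libraries.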

Results

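The series measured gene expression in the quadriceps muscle of mice that carry an additional Ant1 gene and of wild-type mice. Ant1 is now named Slc25a4 and encodes the adenine nucleotide translocase of heart and skeletal muscle, the carrier that exchanges ADP for ATP across the inner mitochondrial membrane. Stranded libraries of polyadenylated RNA were made from 4 WT females, 4 WT males, 4 Tg females and 4 Tg males, all 6 months old. The files hold values taken as estimated counts for 19108 genes, with 17.4 to 30.7 times 1000000 counts per library. The muscle's own transcripts dominated: Myh4, the myosin heavy chain of fast IIb fibres, took 5.33 to 9.998% of all counts, and the 10 most abundant genes took 22.5 to 30.6%. From the series title, the study is about how muscle adapts its protein balance to mitochondrial stress and about muscle wasting.

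Slc25a4 lies on chromosome 8 from 46206797 to 46211284 (ENSMUSG00000031633.4, minus strand, build mm10). Its level was 3399 ± 408 CPM in WT muscle (SD, n = 8) and 9755 ± 876 CPM in Tg muscle (SD, n = 8), a 2.88-fold increase. On the log2 scale the averaged difference was 1.53 (SE 0.08, adjusted p = 4.89e-10). It was 1.68 (SE 0.11) in females and 1.37 (SE 0.11) in males. The difference was not called by the interaction test (-0.32, SE 0.15, adjusted p = 0.678). That p is adjusted over all tested genes, and the test called few of the genes with a small simulated interaction. A smaller increase in males is therefore left open. Counts per gene do not separate the transgene from the endogenous gene. The related Slc25a5, another adenine nucleotide translocase, had a log2 fold change of 0.13 (SE 0.22, adjusted p = 0.673).

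**Figure D1:**
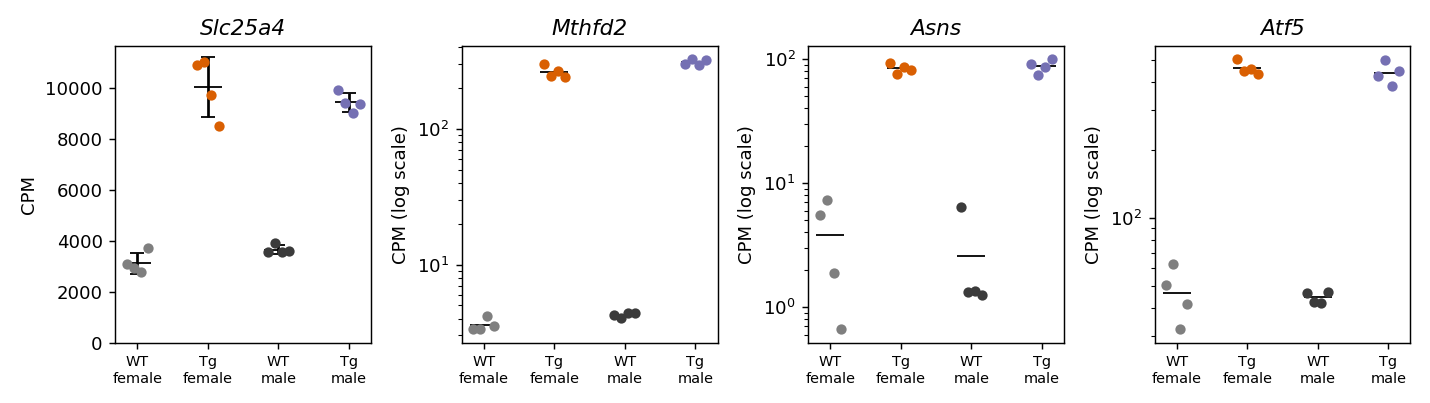
Counts per 1000000 of Slc25a4, Mthfd2, Asns and Atf5 in the 16 libraries, 4 per group; points are libraries and horizontal ticks are group means. The Slc25a4 panel starts at 0 and its bars are ± 1 SD, while the other 3 panels have a log axis and no error bars. Tg libraries lie above all WT libraries of their sex in every panel, with Slc25a4 at 9755 CPM on average against 3399.

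The question of the main comparison is what the transgene changes in muscle, averaged over the sexes. Among genes that passed the naming rule, many of the largest increases were in genes for making and importing amino acids, with the secreted hormones Fgf21 and Gdf15 also among them. Fgf21, a hormone that acts on fasting metabolism, had 5 counts in 3 of 8 WT libraries and 16.5 to 44.1 CPM in Tg libraries, a ratio of 948 (95% counting interval 406 to 2921). Gdf15, a hormone that lowers food intake, had 9 counts in 4 of 8 WT libraries and 2.73 to 5.42 CPM in Tg libraries, a ratio of 89.7 (47.0 to 197). Slc7a11, the cystine transporter, had 3 counts in 2 of 8 WT libraries and 16.98 to 28.2 CPM in Tg libraries, a ratio of 1316 (450 to 6385), or 3537 without WT female 3. Without the 4 libraries rich in adipocyte markers the ratio was 818 for Slc7a11 and 239 for Gdf15, and Fgf21 had 0 counts in WT. In all, 4158 of 13666 tested genes (30.4%) were called, 2344 higher and 1814 lower in Tg, and 456 of them changed by at least 1 on the log2 scale, 291 up and 165 down.

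The other large increases held enzymes and transporters of amino acids. Mthfd2, a mitochondrial enzyme of folate-linked one-carbon metabolism (chromosome 6, 83305691 to 83325908), rose 72.9-fold, from 3.93 ± 0.455 to 287 ± 31.5 CPM (SD, n = 8 each). Slc7a5, a carrier of large neutral amino acids, rose 51.8-fold, Psat1 of serine synthesis 36.1-fold, Asns, which makes asparagine, 27.2-fold, Aldh18a1 of proline synthesis 22.8-fold, and Slc7a3, a carrier of cationic amino acids, 22.4-fold. Trib3, a pseudokinase induced by cell stress, rose 53.2-fold. The remaining genes of this group were Arhgap33 (63.7-fold), the vesicular glutamate transporter gene Slc17a7 (31.4-fold, from 0.121 to 4.08 CPM), the sterol acyltransferase gene Soat2 (20.96-fold) and Trim66 (18.1-fold). In WT males, 1 library stood apart for Psat1 (11.1 CPM against 1.48 to 2.22 in the others) and for Asns (6.42 against 1.24 to 1.34 CPM). Without the 4 adipocyte-rich libraries, this one included, the log2 fold change went from 5.17 to 6.28 for Psat1 and from 4.77 to 6.05 for Asns.

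Among the largest decreases, Tmem132b (chromosome 5, 125531774 to 125792583) fell by 3.65 on the log2 scale (SE 0.30), from 12.1 ± 10.5 to 1.40 ± 1.82 CPM (SD, n = 8 each); its WT spread holds a sex difference described with the sexes. Dkk3, a secreted relative of Wnt inhibitors, fell from 68.6 ± 39.9 to 6.92 ± 2.48 CPM and Odf3l2 from 21.1 ± 7.07 to 2.46 ± 2.60 CPM. The potassium channel gene Kcnf1 fell by 3.08 on the log2 scale, Pld5 by 2.60 and the serine protease gene Htra4 by 2.37. Gbp10 fell by 2.78, with 1 WT female at 16.6 CPM against 2.65 to 4.13 CPM in the others. The calcium channel subunit gene Cacna2d4 (-3.53) and Lrtm2 (-2.66) overlap on opposite strands. Whether counting used the strand of the reads is not known, so which of them fell is uncertain. Other genes named below also overlap another gene, such as Atf5, Aldh1l2, Chchd10, Cox6a2, Hspb6, Itga7, Tnnc1 and Myh7b on opposite strands. Dnaja3 overlaps Vasn and Igtp overlaps Irgm2 on the same strand. Their values may hold reads of the overlapping gene.

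Lists of the integrated stress response and of amino acid supply rose. Of 20 genes of the list of ATF4 and stress-response regulators, 17 were higher and 1 lower, and 18 and 1 adjusted over the list alone (camera adjusted p = 3.76e-63, and 3.27e-06 with an estimated correlation). Atf5, a transcription factor of the mitochondrial stress response, rose from 45.5 ± 8.64 to 451 ± 39.8 CPM, Atf4 itself 2.22-fold, and Pck2, the mitochondrial phosphoenolpyruvate carboxykinase gene, 6.24-fold. Of 14 genes of serine, one-carbon, proline and asparagine synthesis, 12 were higher and 0 lower, and 13 and 0 adjusted over the list alone (adjusted p = 3.76e-63, and 5.57e-07 with an estimated correlation); Pycr1 of proline synthesis rose 8.23-fold and Aldh1l2, a mitochondrial folate enzyme, 5.11-fold. Of 12 amino acid transporter genes, 7 were higher and 1 lower, with the same numbers adjusted over the list alone (adjusted p = 1.68e-36, and 3.31e-05 with an estimated correlation). Slc7a1, a carrier of cationic amino acids, rose 13.98-fold and Slc3a2, the shared heavy chain of several carriers, 3.06-fold. The list of cytosolic aminoacyl-tRNA synthetases, the enzymes that load tRNAs, also holds the export receptor Xpot. Of its 21 genes, 18 were higher and 0 lower by both counts, over all genes and adjusted over the list alone (adjusted p = 2.90e-41, and 0.00803 with an estimated correlation). Gars rose 3.37-fold, Sars 2.61-fold, Lars 2.43-fold and Xpot, the tRNA export receptor, 2.82-fold.

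In the lists of oxidative stress and p53 targets, members were called in both directions. Among 22 genes of the oxidative stress (NRF2) list, 10 were higher and 1 lower, and 10 and 2 adjusted over the list alone (adjusted p = 1.42e-05, and 0.0308 with an estimated correlation). The median log2 fold change of the list was 0.11 and its mean 0.61. Its largest value in each sex (9.44 in females, 10.5 in males) is also the largest of the amino acid transporter list, so both lists hold that gene. Srxn1, which repairs peroxiredoxins, rose 3.57-fold, and the glutathione enzymes Gsr and Gpx4 rose 1.35-fold and 1.47-fold. Of 14 p53 target genes, 6 were higher and 4 lower, and 7 and 5 adjusted over the list alone; Sesn2 rose 10.5-fold and Cdkn1a, an inhibitor of the cell cycle, 4.16-fold, while Polk, a DNA polymerase, fell by 1.44 on the log2 scale. The call of the list p53 target genes (adjusted p = 0.00304, direction up) was lost with an estimated correlation (adjusted p = 0.124), on ranks (0.512) and without the 4 adipocyte-rich libraries (0.0592).

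Many genes of the protein synthesis machinery were higher, mostly by small amounts, but none of the list calls here held with an estimated correlation. Of 86 cytosolic ribosomal protein genes, 77 were higher and 0 lower, and 79 and 0 adjusted over the list alone, with a median log2 fold change of 0.41; Rpl12 rose 1.77-fold. The list's adjusted p was 5.74e-27 (adjusted p = 0.172 with an estimated correlation). Of 40 translation factor genes, 22 were higher and 3 lower, and 23 and 5 adjusted over the list alone. Eif3c, a subunit of the initiation factor eIF3, rose 3.29-fold, from 182 ± 8.92 to 600 ± 30.8 CPM, and Eif1, which takes part in start codon choice, 1.37-fold (list adjusted p = 0.000187, and adjusted p = 0.553 with an estimated correlation). Of 78 mitochondrial ribosomal protein genes, 35 were higher and 3 lower, and 39 and 4 adjusted over the list alone, with a median of 0.15. Mrps18b rose 1.43-fold and Mrpl3 1.32-fold (list adjusted p = 0.00304, and adjusted p = 0.845 with an estimated correlation).

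Among genes of protein folding and breakdown, 3 lists were called higher at the preset correlation. Of 22 genes of mitochondrial chaperones and proteases, 13 were higher and 1 lower, and 14 and 2 adjusted over the list alone. Hspa9, the mitochondrial Hsp70, rose 2.44-fold, its partner Dnaja3 1.60-fold, Chchd10, a protein of the intermembrane space, 2.53-fold and the matrix protease gene Lonp1 1.49-fold (list adjusted p = 1.42e-05, and adjusted p = 0.196 with an estimated correlation). Of 23 genes of the endoplasmic reticulum unfolded protein response, 11 were higher and 1 lower, and 13 and 1 adjusted over the list alone. The sensor genes Ern1 and Atf6 rose 4.06-fold and 1.97-fold and Herpud1 2.14-fold, while the chaperone gene Dnajc3 fell by 0.37 on the log2 scale (list adjusted p = 0.000455, and adjusted p = 0.320 with an estimated correlation). Of 7 genes of the list Small heat shock proteins, 4 were higher and 0 lower by both counts, over all genes and adjusted over the list alone; Hspb6 rose 2.30-fold and Hspb7, whose WT level was 112 ± 73.5 CPM, 4.87-fold. That list's call (adjusted p = 0.0312) was lost with an estimated correlation (adjusted p = 0.499), on ranks (0.0506), with 1 surrogate variable (0.0883), with the adipocyte marker covariate (0.0731), without WT male 1 (0.0565) and without the 4 libraries rich in adipocyte markers (0.106).

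Other lists of protein turnover were not called, though single members were. Of 34 proteasome subunit genes, 13 were higher and 3 lower by both counts (adjusted p = 0.132), with Psmd11 1.28-fold higher. Of 37 lysosomal genes, 10 were higher and 2 lower, and 11 and 6 adjusted over the list alone (adjusted p = 0.222); the protease gene Ctsl rose 2.78-fold and Atp6v1h, of the proton pump, 1.85-fold. Of 27 autophagy genes, 9 were higher and 3 lower, and 9 and 4 adjusted over the list alone (adjusted p = 0.367); Map1lc3a rose 1.81-fold and the cargo receptor gene Sqstm1 1.39-fold. Of 29 cytosolic chaperone genes, 5 were higher and 1 lower by both counts (adjusted p = 0.425), and Cct3 rose 1.14-fold (not called without the 4 adipocyte-rich libraries, adjusted p = 0.0644). The list Immunoproteasome and antigen presentation had 0 higher and 1 lower of 11 by both counts (adjusted p = 0.222), the proteasome activator gene Psme1, which fell by 0.45 on the log2 scale. For the list Mitochondrial protein import, 10 of 29 genes were higher and 2 lower, and 11 and 2 adjusted over the list alone; Timm10 rose 1.62-fold. Its adjusted p was 0.0567, 0.00309 with fry, 0.0125 on ranks, and between 0.0225 and 0.0446 without WT female 1, WT female 4, Tg female 2, Tg male 2 or Tg male 3.

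Markers of muscle wasting did not move together. Of 25 muscle atrophy genes, 5 were higher and 5 lower, and 6 and 6 adjusted over the list alone (adjusted p = 0.946); the median was -0.14 and the mean 0.09. Fbxo32, the atrogin-1 ubiquitin ligase, fell from 927 ± 272 to 472 ± 75.8 CPM, while the metallothionein gene Mt2 rose 3.28-fold. Of 19 denervation-responsive genes, 11 were higher and 3 lower, and 12 and 4 adjusted over the list alone. Ankrd1, a stretch-responsive protein, rose 15.5-fold, Gadd45a 7.91-fold, the acetylcholine receptor subunit gene Chrnb1 2.21-fold and Musk, the receptor kinase of the neuromuscular junction, 2.02-fold (list adjusted p = 9.08e-07, and adjusted p = 0.0526 with an estimated correlation). In the list Muscle-secreted and growth-control genes, 5 of 23 were higher and 4 lower, and 6 and 4 adjusted over the list alone. Besides Fgf21 and Gdf15, Igf2, a fetal growth factor, rose 2.66-fold and Myc 3.16-fold. The test of this list pointed up (adjusted p = 0.0443) while its median was -0.04 and its mean 0.68. Its call was lost with an estimated correlation (adjusted p = 0.273), on ranks (0.976), with a CPM filter (0.0607), with 1 surrogate variable (0.0587), with the adipocyte marker covariate (0.0525), without the 4 adipocyte-rich libraries (0.0741) and without WT female 2, WT female 4, WT male 1, WT male 2 or WT male 4 (adjusted p between 0.0521 and 0.114).

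Genes of slow fibres were higher on average, with a wide spread between libraries. Of 16 slow fibre genes, 9 were higher and 0 lower, and 10 and 0 adjusted over the list alone, with a median of 1.89. Casq2, the calcium store protein of slow muscle, rose from 11.5 ± 6.41 to 34.7 ± 10.1 CPM and Myh7b 3.76-fold. Myoz2 rose 6.05-fold with 1 WT female at 33.5 CPM against 0.587 to 3.42 CPM in the others, and Tnnc1, the slow troponin C, 10.9-fold with 1 Tg female at 57.1 CPM against 1.45 to 6.77 CPM. On the log2 scale Tnnc1 went from 3.44 to 2.37 without Tg female 2, 4.21 without WT female 2 and 6.91 without the 4 adipocyte-rich libraries, and limma-voom did not call it (adjusted p = 0.0576). Myoz2 went from 2.60 to 3.64 without WT female 2, 3.86 without the 4 libraries and 3.36 with limma-voom, and Myh7b from 1.91 to 2.61, 3.98 and 2.68 in the same settings. The mean of the list per library ran from -3.05 to 2.82 in log2 units around the mean of all libraries. An exact permutation test of this mean within the sexes gave a difference of 1.92 (p = 0.00653, 0.0784 adjusted over 12 such scores). The list's adjusted p was 0.0152 (adjusted p = 0.845 with an estimated correlation). In the list Fast fibre genes, 1 of 17 was higher and 7 lower, and 2 and 9 adjusted over the list alone. Myh4 fell from 92045 ± 14533 to 64100.1 ± 12970.3 CPM, and Tpm1 fell by 0.58 on the log2 scale. The list's adjusted p was 0.0764, 0.00682 without the 4 adipocyte-rich libraries, 0.0274 with 1 surrogate variable, 0.0169 on ranks, and between 0.0145 and 0.0452 without WT female 2, Tg female 1, Tg female 2 or Tg male 2.

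Regeneration lists had calls in both directions. Of 14 myogenic and regeneration genes, 5 were higher and 3 lower, and 6 and 3 adjusted over the list alone (adjusted p = 0.468), and the transcription factor gene Myog rose 2.25-fold. Of 10 satellite cell markers, 2 were higher and 2 lower, and 2 and 3 adjusted over the list alone (adjusted p = 0.946); Itga7, an integrin of muscle, rose 1.91-fold and Chodl fell by 1.07 on the log2 scale.

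Lists of mitochondrial energy metabolism were not called. Of 36 complex I genes, 3 were higher and 3 lower, and 1 and 2 adjusted over the list alone (adjusted p = 0.972), with Ndufa7 at 1.19-fold. Of 42 genes of complexes II to V, 11 were higher and 4 lower, and 14 and 5 adjusted over the list alone (adjusted p = 0.402). Cox6a2, the muscle form of a cytochrome c oxidase subunit, rose from 508 ± 104 to 1281 ± 100.4 CPM and Cox7a2 1.34-fold, while Cox8b, another subunit of that enzyme, fell by 0.45 on the log2 scale. In the tricarboxylic acid cycle, 2 of 19 were higher and 2 lower by both counts (adjusted p = 0.937); Idh2 rose 2.03-fold and Pcx, the pyruvate carboxylase gene, fell by 0.70 (not called in a model without sex, adjusted p = 0.0510). For fatty acid oxidation, 1 of 25 was higher and 2 lower by both counts (adjusted p = 0.719); Ucp3 fell by 1.04 and Pdk4, which inhibits pyruvate dehydrogenase, by 0.78. Of 18 mitochondrial biogenesis regulators, 3 were higher and 0 lower by both counts (adjusted p = 0.212); the coactivator gene Pprc1 rose 1.39-fold and the nuclear receptor gene Esrrg from 11.3 ± 7.26 to 65.2 ± 17.5 CPM.

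The list Polyamine metabolism was called lower, but not on ranks (adjusted p = 0.236). Of its 12 genes, 2 were higher and 5 lower, and 3 and 6 adjusted over the list alone (adjusted p = 0.00114, and 0.0221 with an estimated correlation). Amd1, which makes decarboxylated S-adenosylmethionine, the donor for spermidine and spermine, fell by 1.89 on the log2 scale (SE 0.10). Amd2, nearly identical in sequence, showed the same value, so it is uncertain which of them fell. The same reads may thus enter the test of this list through both genes, in every comparison. The list without either of them was not tested. The spermine oxidase gene Smox fell by 0.88 (not called in a model without sex, adjusted p = 0.182), and the spermidine synthase gene Srm rose 1.60-fold. For glycolysis and glycogen, 2 of 22 were higher and 6 lower, and 2 and 7 adjusted over the list alone (adjusted p = 0.425), with the glycogen branching enzyme gene Gbe1 up 3.24-fold. Of 18 genes of cholesterol and sterol synthesis, 2 were higher and 3 lower by both counts (adjusted p = 0.690); Mvd rose 1.85-fold.

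The list Interferon-induced genes was called lower (adjusted p = 0.0127), but not with an estimated correlation (adjusted p = 0.897), with fry (0.0559), without WT female 3 (0.0529) or without the 4 adipocyte-rich libraries (0.0701). Its median was -0.50 in females and -0.07 in males, and the interaction test of the list gave an adjusted p of 6.75e-10 (adjusted p = 0.649 with an estimated correlation). Among the 27 Interferon-induced genes, 1 was higher and 6 lower, and 1 and 3 adjusted over the list alone; Igtp fell by 0.78 and Gbp7 by 0.72 on the log2 scale, and Ifit3 rose 1.69-fold. Of 10 tested inflammatory cytokine and chemokine genes, 2 were higher and 0 lower by both counts (adjusted p = 0.937), and Relb rose 1.46-fold; the median was -0.04 and the mean 0.03. The neutrophil gene S100a8, the only tested marker of lymphocytes and neutrophils, rose from 0.126 to 0.575 CPM (2.16 on the log2 scale, and 2.92 without the 4 adipocyte-rich libraries).

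Markers of other cell types gave few calls. The 18 macrophage markers had 0 higher and 0 lower by both counts, with a median of -0.48; the adjusted p of Macrophage markers was 0.0552, 0.00112 on ranks, and between 0.00507 and 0.0452 without WT female 1, WT female 4, Tg female 2, Tg female 4, WT male 2 or Tg male 3. None was called by either count among 17 fibro-adipogenic and fibroblast markers (adjusted p = 0.209), 27 extracellular matrix genes (0.381; Dcn at 474 ± 129 and 389 ± 113 CPM in WT and Tg), 15 endothelial markers (0.937; Cdh5 at 74.4 ± 13.1 and 81.2 ± 6.94 CPM, called without the 4 adipocyte-rich libraries at 0.28 on the log2 scale, adjusted p = 0.00256), 9 tendon and cartilage markers (0.815; Fmod at 127 ± 64.9 and 142 ± 63.5 CPM) or 15 adipocyte markers (0.690; Fabp4 at 567 ± 561 and 323 ± 174 CPM). For the endothelial markers the median was -0.01 and the mean 0.03. By both counts, 1 of 12 smooth muscle and pericyte markers was higher and 0 lower (adjusted p = 0.963), as was 1 of 10 Schwann cell and nerve markers (adjusted p = 0.532), namely Cnp, 1.26-fold. Of 9 red blood cell markers, 1 was higher and 1 lower, and 2 and 1 adjusted over the list alone (adjusted p = 0.937), with Bpgm, which makes bisphosphoglycerate, 0.62 lower on the log2 scale. Adipocyte markers were high in 4 libraries of both genotypes, with list means of 2.87 in WT female 2, 2.61 in WT female 1, 2.33 in WT male 1 and 2.02 in Tg female 4, in log2 units around the mean of all libraries; the next was 0.85.

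**Figure D2:**
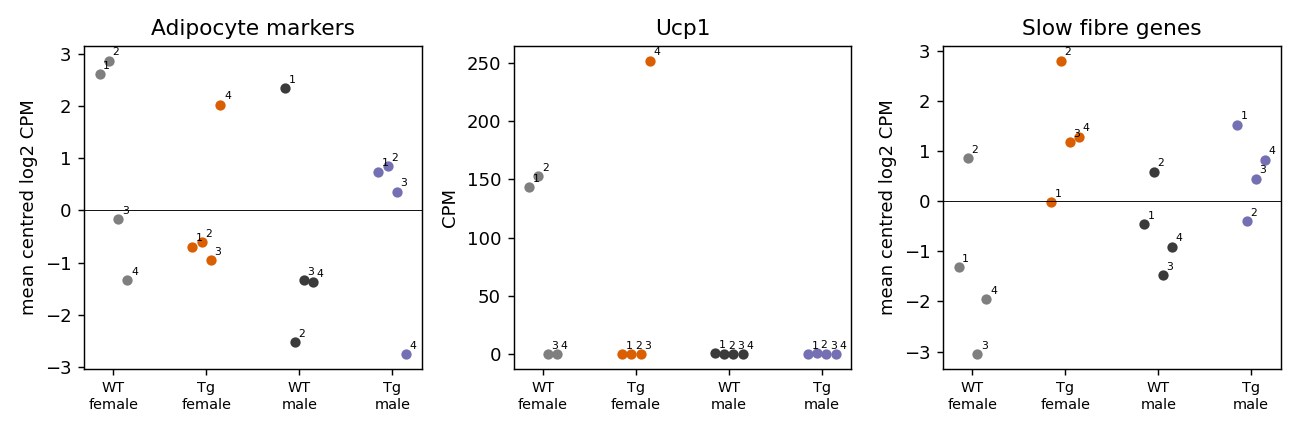
Mean of the adipocyte markers (log2 CPM centred on all libraries), Ucp1 in counts per 1000000, and the mean of the slow fibre genes (log2 CPM centred in the same way) in each of the 16 libraries, 4 per group; points are libraries and the digit beside each is its replicate number. Adipocyte markers are highest in WT female 2, WT female 1, WT male 1 and Tg female 4, and slow fibre means run from -3.05 to 2.82.

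Lists that record handling or time of day were not called as lists. Of 21 immediate early genes, 9 were higher and 1 lower by both counts; Egr1 rose 2.71-fold. Their adjusted p was 0.0552, 0.0422 with RLE normalization, 0.00133 with fry, 0.0368 on ranks, and between 0.0239 and 0.0499 without WT female 1, WT female 4, Tg female 1, Tg female 2, Tg female 3, WT male 3, WT male 4 or Tg male 1 (list Immediate early genes). Among 18 clock genes, 6 were higher and 5 lower by both counts (adjusted p = 0.751), where 30.4% of all tested genes were called. Ciart was up 2.24-fold and Hlf down by 0.89 on the log2 scale (-0.89). The camera test looks for a shift in 1 direction, so it cannot show that clock genes, called in both directions, did not change. Fry without regard to direction, which does not compare a list with other genes, gave adjusted p of 1.79e-07 in females and 1.48e-08 in males. Of 9 genes of the Y-linked and X-inactivation list, 1 was higher and 1 lower by both counts (adjusted p = 0.937; median 0.08, mean 0.10, test down).

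In the averaged effect, 17 of 47 lists were called, 15 higher and 2 lower. As many lists were called in 46 of 100 splits of the libraries, the real one included. A call or p at the preset correlation alone is therefore weak evidence for a list. The calls that held with an estimated correlation were the 6 lists of serine and one-carbon synthesis, ATF4, aminoacyl-tRNA synthetases, amino acid transporters, NRF2 and polyamine metabolism. The lists are not independent. NRF2 and amino acid transporters share the gene with their largest increase, as do ATF4 and the list Muscle-secreted and growth-control genes (8.86 in females, 10.8 in males). Other lists passed the threshold only on ranks, namely Proteasome subunits (0.0211) and Fibro-adipogenic and fibroblast markers (0.0368), or only with fry, namely Mitochondrial biogenesis regulators (0.000871), Lysosomal genes (0.00368), Autophagy genes (0.0108), Myogenic and regeneration genes (0.0171) and Cytosolic chaperones (0.0430). In 1480 genes, 10.8% of those tested and 35.6% of those called, every Tg library lay beyond every WT library of its sex in the same direction in both sexes, where chance gives 0.0408% of tested genes. Without the 4 adipocyte-rich libraries 3945 genes were called, and 77.1% of the 4158 were among them; 49.8% of the calls were then higher in Tg, against 56.4% with all libraries.

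**Figure D3:**
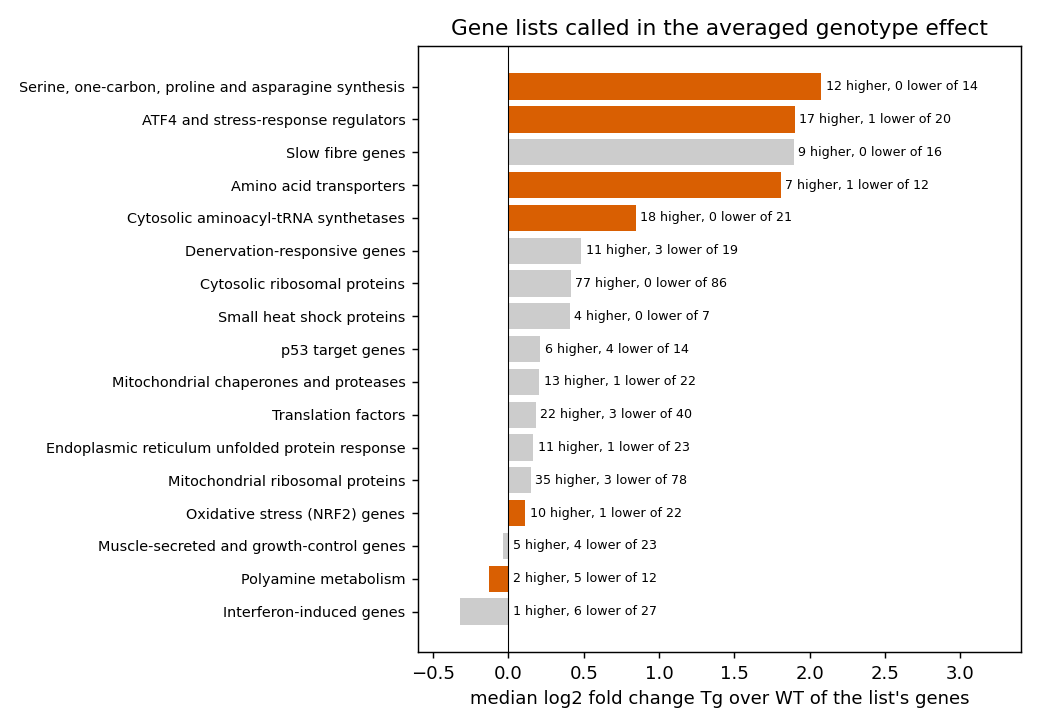
Median log2 fold change, Tg over WT averaged over the sexes, of the genes in each of the 17 called lists, with the number of genes called higher and lower of those tested printed beside each bar. Orange bars mark the 6 lists whose call held with an estimated correlation between genes and grey bars those whose call did not; the median is highest for serine, one-carbon, proline and asparagine synthesis (2.08).

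In females alone, the same amino acid and stress genes rose. Mthfd2 rose by 6.20 on the log2 scale (SE 0.10), Slc7a5 by 5.61, Asns by 4.43, Atf5 by 3.31 and Atf4 by 1.32. Of 13666 genes, 2416 were called, 1382 higher and 1034 lower, and 511 changed by at least 1 on the log2 scale. The call covered 23 of 47 lists, of which 5 held with an estimated correlation: ATF4 regulators, serine and one-carbon synthesis, aminoacyl-tRNA synthetases, amino acid transporters and NRF2 genes. The other 18 were lost, with adjusted p of 0.0695 to 0.791 with an estimated correlation. Macrophage markers were among these, with 0 higher and 3 lower of 18 (0.602), and so were Interferon-induced genes, with 0 higher and 9 lower of 27 (0.474). In 2466 genes (18.0%) the female Tg libraries lay all above or all below the female WT libraries, against 2.86% by chance. A fit on the female libraries alone called 1404 genes. Of the 4 female and male libraries rich in adipocyte markers, 3 were female, and without the 4 libraries 1809 genes were called, with 59.3% of the 2416 among them. The share of higher calls was 57.2% with all libraries, 50.5% without the 4 libraries and 51.9% with 1 surrogate variable.

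In males alone, Mthfd2 rose by 6.18 on the log2 scale, Slc7a5 by 5.78, Asns by 5.10, Atf5 by 3.31 and Atf4 by 0.98. Of 13666 genes, 2492 were called, 1346 higher and 1146 lower, and 480 changed by at least 1 on the log2 scale. Lists called numbered 14, of which 5 held with an estimated correlation: serine and one-carbon synthesis, ATF4 regulators, amino acid transporters, aminoacyl-tRNA synthetases and polyamine metabolism. The other 9 had adjusted p of 0.0902 to 0.960 with an estimated correlation. In 3513 genes (25.7%) the male Tg libraries lay all above or all below the male WT libraries, against 2.86% by chance. Of the male calls 54.0% were higher, but 45.8% with RLE normalization, 46.2% with DESeq2, 48.4% without WT male 1 and 44.9% without the 4 adipocyte-rich libraries.

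Female and male effects were alike across genes. The log2 fold changes correlated with Pearson r = 0.66 and Spearman rho = 0.56 over 13666 genes, which are not independent replicates. Over the genes called in the averaged effect r was 0.90, but these were chosen for their mean over both sexes, which favours agreement. Of the genes called in females, 94.5% had the same sign in males, and of those called in males, 96.0% had the same sign in females. Over all tested genes the share with the same sign was 72.3%. Both sexes called 882 genes higher, where 136 would be called by chance, and 586 lower, where 86.7 would be; 6 were called in opposite directions. Over all tested genes, leaving out 1 library gave r between 0.485 and 0.703, with a jackknife SE of 0.206 over the 16 libraries. Leaving out the 4 adipocyte-rich libraries gave 0.576.

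**Figure D4:**
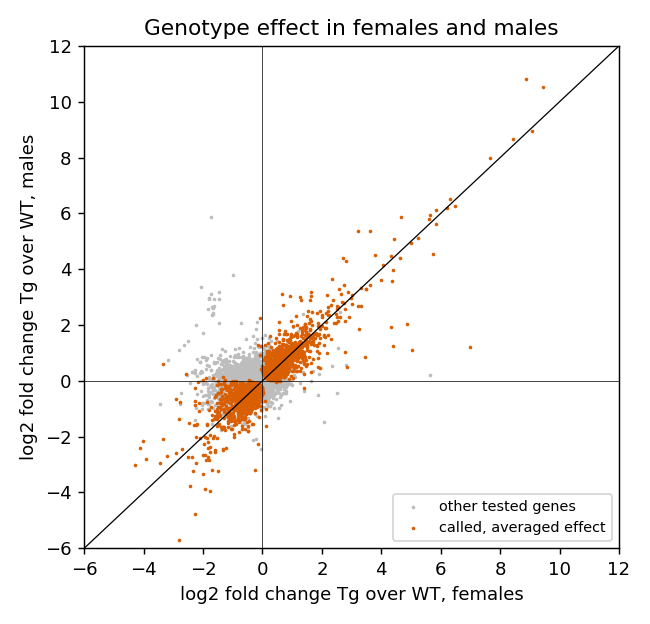
Log2 fold change, Tg over WT, of 13666 tested genes in females (horizontal axis) and males (vertical axis), with the line of equal change; each point is 1 gene, orange if called in the averaged effect and grey otherwise. The called genes lie along the line (r = 0.90), but they were chosen for their mean over both sexes, which favours agreement. In both sexes 882 genes were called higher and 586 lower.

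Whether the genotype effect differs between the sexes was tested by the interaction. Itpr1, an inositol trisphosphate receptor that releases stored calcium (chromosome 6, 108213096 to 108551109), fell in both sexes and was the only gene called. Its log2 fold change was -0.69 in females and -1.61 in males, a difference of -0.92 (SE 0.13, adjusted p = 0.0272). In edgeR 1015 genes had an unadjusted p under 0.05, where 683.3 are expected by chance, and 87 genes were called by DESeq2 and 1 by limma-voom. The call (Itpr1, interaction) was lost with upper-quartile normalization (adjusted p = 0.0507) and without Tg female 3, WT male 2, WT male 3, WT male 4, Tg male 1, Tg male 2 or Tg male 3 (adjusted p of 0.0568 to 0.112). The count of called genes was 23 without Tg male 4, 5 without WT female 3, 3 without WT female 2, and 2 without WT female 1 or WT female 4. It was 0 without Tg female 3, WT male 2, WT male 4, Tg male 1, Tg male 2 or Tg male 3. At a preset correlation 19 lists were called, 6 in the direction of a higher male effect and 13 in that of a lower one, but with an estimated correlation only polyamine metabolism was (adjusted p = 4.38e-05 preset and 0.0209 estimated). Amd1 fell by 1.32 in females and by 2.46 in males, and the difference between these was not called (adjusted p = 0.0572). The list call may rest in part on the near copies Amd1 and Amd2, and the list without either was not tested.

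In wild-type muscle, Slc30a2, C7 and several Mup genes were among those that differed between males and females. Slc30a2, a zinc transporter, was at 0.649 ± 0.257 CPM in WT females and 16.9 ± 1.16 CPM in WT males, and C7, the complement component, at 0.948 ± 0.543 and 15.9 ± 4.38 CPM (SD, n = 4 each). Log2 differences were 3.24 for 1700001O22Rik, 3.16 for Tmem132b and 2.61 for Npnt, all higher in males. Among genes lower in males were Mup1, Mup2, Mup9, Mup14 and Mup15, the genes of major urinary proteins; Mup2 was at 98.5 ± 45.6 CPM in females and 1.55 ± 1.64 CPM in males (Mup2, sex difference in wild type: -5.93 on the log2 scale, -6.80 without WT male 4, -5.19 without the 4 adipocyte-rich libraries and -6.71 with limma-voom). These genes are close copies of each other, so how the counts divide among them is uncertain. Besides the list of sex-linked genes, polyamine metabolism was higher in males, with 4 genes higher and 1 lower of 12 (adjusted p = 4.81e-15, and 7.28e-05 with an estimated correlation). In all, 501 genes were called, 275 higher and 226 lower in males, and 178 differed by at least 1 on the log2 scale. Of 6 lists called, the polyamine and the sex chromosome list held with an estimated correlation. The count was 292 without WT male 2, 326 without WT male 4 and 807 with DESeq2. Without the 4 adipocyte-rich libraries it was 466, with 54.1% of the 501 genes among them.

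In transgenic muscle, the sex difference included many of the same genes. C7 was at 0.445 ± 0.269 CPM in Tg females and 11.7 ± 6.43 CPM in Tg males, and Slc30a2 at 0.733 ± 0.102 and 10.1 ± 3.24 CPM (SD, n = 4 each). Tmem132b, 1700001O22Rik and Actr3b were also higher in males, by 4.42, 3.76 and 2.87 on the log2 scale. The noncoding transcripts Rian and H19 were lower in males (-1.25 and -1.24), as were Rhpn2 (-1.25), Rhobtb1 (-1.13) and the adenylate kinase gene Ak4 (-1.07); Rhobtb1 was no longer called without Tg male 2 (adjusted p = 0.0553). In all, 72 genes were called, 48 higher and 24 lower in males, and 42 differed by at least 1. Outside the list of sex-linked genes the count was 63, against 492 in WT, and 49 were shared in the same direction, where 1.18 are expected by chance. Of 14 lists called, the sex chromosome list and polyamine metabolism (adjusted p = 2.41e-06, and 0.00269 with an estimated correlation) held with an estimated correlation. The count of 72 was 43 without Tg female 1, 46 without Tg female 2, 45 without Tg male 2, 166 with DESeq2, 129 with a surrogate variable, and 150 without the 4 adipocyte-rich libraries.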

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

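Tests chosen only after the result was seen were those on adipose RNA, that is the runs without the 4 adipocyte-rich libraries, the further fat genes and the comparison of the adipocyte markers between genotypes, and the gap test on Ucp1 and other genes outside the naming rule.

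In 4 libraries of both genotypes, adipocyte markers stood far above the rest: 2.87 in WT female 2, 2.61 in WT female 1, 2.33 in WT male 1 and 2.02 in Tg female 4, against 0.85 at most in the others. In 17 fat genes that the marker list does not hold, the median excess of the 4 libraries over the other 12 was 2.76 on the log2 scale (Scd1 at 3388 against 592 CPM, Fasn at 1692 against 87.0 CPM), which is consistent with RNA of fat tissue in the muscle pieces. Ucp1, a brown fat gene, was at 143, 153 and 252 CPM in WT female 1, WT female 2 and Tg female 4 but at 0.535 CPM in WT male 1, so the fat may differ in kind. The 4 libraries do not account for most of the genotype calls, since 77.1% of the 4158 genes were called in the same direction without them. That run is not free of adipose differences. Marker means were -1.33 to -2.53 in the remaining WT males, 0.36 to 0.85 in Tg male 1, Tg male 2 and Tg male 3, and -2.75 in Tg male 4. With the marker mean as a covariate, 99.6% of the 4158 were called in the same direction. Whether the genotypes differ in fat cannot be told apart from chance sampling here (exact permutation p = 0.78 within the sexes, 4900 exchanges, 8 libraries per genotype), and muscle fat as a trait of single animals stays open, as untested.

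Cytosolic ribosomal protein genes were higher in Tg, 77 of 86 by small amounts. They are short, with a median exonic length of 1737 bases against 4438 over tested genes, but they exceeded genes matched on length and level by a median of 0.40 (interquartile range 0.29 to 0.49), nearly their unmatched 0.41, which argues against a trend with length. With RLE factors, and without the most abundant genes, 77 were called higher in both, so the count did not depend on these choices. They moved the median log2 fold change over all tested genes little (-0.031 and -0.0087, against -0.012). They are therefore weak tests of the normalization as a cause. RNA quality and time of dissection stay open, as the labels hold no measure of them. Clock genes (6 higher and 5 lower of 18, adjusted p = 0.751) and immediate early genes (9 higher and 1 lower of 21, adjusted p = 0.0552) were not called as lists. That test looks for a shift in 1 direction, so it does not speak against a change of clock genes in both directions. The call of the ribosomal list was lost with an estimated correlation (adjusted p = 0.172). A biological change with the genotype may remain, as a hypothesis.

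Fewer genes were called between the sexes in Tg (72, and 43, 46 and 45 without Tg female 1, Tg female 2 and Tg male 2) than in WT (501, and 292 and 326 without WT male 2 and WT male 4). The ratio of the counts fell from 6.96 to 2.81 (228 and 81) with each genotype fitted alone. It fell to 3.11 (466 and 150) without the 4 adipocyte-rich libraries, so part of the gap goes with each of these settings. The remaining ratios argue against a shared estimate of the spread or those 4 libraries as its whole cause. Adipose RNA in the other libraries stays open. Sizes of the difference do not decide, since each set of called genes was chosen for its value in 1 genotype: medians in WT and Tg were 1.08 and 1.07 on the log2 scale for genes called in Tg, and 0.72 and 0.26 for those called in WT. The interaction called 1 gene, so a weaker sex difference in Tg may hold but was not shown.

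Other splits of the same libraries were drawn to see whether other groups of the same animals give as much. For the averaged effect, 1 of 100 splits, the real one, called as many as 4158 genes and the highest other called 1392, so chance is unlikely. In females, 1 of 35 splits, the real one, called as many as 2416 genes. The highest other called 1110 and exchanges Tg female 4 with WT female 4. In males, 1 of 35 splits called as many (2492, and 0 in the highest other), as for the sex difference in Tg (72 and 0). The 72 include the 9 genes of the Y-linked and X-inactivation list, whose call the sex labels fix in advance. Outside this list 63 genes were called, against 0 of any kind in the other splits. The real split alone is the smallest share that 35 splits allow, so in these comparisons chance is unlikely but not excluded. For the sex difference in WT, 2 of 35 splits called as many as 501 genes. The other one called 1000 and exchanges WT male 1 with WT female 4, which sets the 3 adipocyte-rich WT libraries and WT female 3 against the rest, so it points to a structure of the samples and chance cannot be excluded. For the interaction, 8 of 100 splits called 1 gene or more and the highest other called 422. That split keeps WT female 1, WT female 2 and WT male 1 together, again a structure of the samples, and chance cannot be excluded. The interaction splits exchange the sex labels within each genotype, which also mixes real sex differences into the spread. They are therefore only a rough guide to what chance gives for the interaction, for genes and for lists. The interaction count also moved when 1 library was left out: 23 without Tg male 4, 5 without WT female 3, 3 without WT female 2, 2 without WT female 1 or WT female 4, and 0 without Tg female 3, WT male 2, WT male 4, Tg male 1, Tg male 2 or Tg male 3. For the number of called lists, 46 of 100 splits reached 17 in the averaged effect, up to 27, and 22 of 100 reached 19 in the interaction, up to 25, so chance cannot be excluded for either number. List calls and p values at the preset correlation alone are therefore weak evidence for single lists too.

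By a test of the gap to the nearest library, 41 of 556 groups of 4 held a library apart from the others, where chance gives about 1 in 20, or 27.8. In CPM, with the range of the other 3 libraries in brackets, these were as follows. WT female 1 had Myog at 6.51 (2.94 to 3.12). WT female 2 had Gbp10 at 16.6 (2.65 to 4.13) and Myoz2 at 33.5 (0.587 to 3.42). WT female 3 had Lonp1 at 89.1 (109 to 111), Dnajc3 at 66.4 (52.2 to 53.7), Gpx4 at 193 (255 to 262), Timm10 at 8.65 (12.1 to 12.3), Ucp3 at 437 (227 to 258) and Itga7 at 60.1 (74.1 to 76.1). WT female 4 had Mrps18b at 40.2 (31.9 to 33.1). Tg female 1 had Slc7a11 at 28.2 (16.98 to 17.5), Dnaja3 at 206 (190.7 to 191), Myh7b at 2.65 (5.37 to 5.73), Cox6a2 at 1385 (1203 to 1225) and Cct3 at 99.9 (93.3 to 94.1). Tg female 2 had Ern1 at 39.2 (35.4 to 36.0) and Tnnc1 at 57.1 (1.45 to 6.77). Tg female 3 had Ak4 at 22.3 (14.3 to 14.8). Tg female 4 had Ifit3 at 10.6 (13.6 to 14.1), Fabp4 at 623 (181 to 195) and Ucp1 at 252 (0 to 0.0351), and its mean of adipocyte markers was 2.02 (-0.96 to -0.61). WT male 1 had Psat1 at 11.1 (1.48 to 2.22), Asns at 6.42 (1.24 to 1.34), Aldh1l2 at 5.62 (8.70 to 9.27), Sesn2 at 4.55 (2.77 to 2.94) and Fabp4 at 1511 (146 to 177). WT male 2 had Tnnc1 at 2.81 (0.545 to 0.758) and Ciart at 12.3 (7.04 to 7.88). Tg male 2 had Aldh1l2 at 44.3 (46.4 to 46.8) and Ern1 at 22.1 (29.8 to 31.1), and Tg male 3 had Myc at 14.5 (11.6 to 11.98). Tg male 4 had Psat1 at 163 (142 to 145), Soat2 at 11.9 (9.12 to 9.53) and Relb at 14.1 (10.6 to 10.8), and its mean of adipocyte markers was -2.75 (0.36 to 0.85). Of the 41, 5 do not show that a library stood apart. These were Slc7a11 at 0.107 in WT female 3 and 0.0476 in WT male 2, Fgf21 at 0.0446 in WT male 1 and Ucp1 at 0.535 in WT male 1, where the other 3 libraries were at 0, which fixes the outcome of the test, and Tmem132b at 0.165 in Tg female 4 (0.100 to 0.109), which rests on a few counts.

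Differences between the sexes in the genotype effect were called by the interaction for Itpr1 (-0.92 on the log2 scale) and, at the preset correlation, for 19 lists. Adjusted p values of lists with a lower effect in males were 6.75e-10 for complex I, 1.23e-08 for complexes II to V, 4.47e-06 for mitochondrial ribosomal proteins, 4.38e-05 for polyamine metabolism, 0.000138 for slow fibre genes, 0.00373 for immediate early genes, 0.00714 for clock genes, 0.00732 for mitochondrial protein import, 0.00798 for proteasome subunits, 0.00911 for aminoacyl-tRNA synthetases, 0.0272 for fast fibre genes, 0.0450 for the tricarboxylic acid cycle and 0.0492 for tendon and cartilage markers. Those of lists with a higher effect in males were 6.75e-10 for interferon-induced genes, 1.23e-08 for macrophage markers, 0.000110 for extracellular matrix genes, 0.000145 for fibro-adipogenic and fibroblast markers, 0.00943 for the immunoproteasome and antigen presentation and 0.0272 for adipocyte markers. With an estimated correlation the adjusted p was 0.0209 for polyamine metabolism, 0.696 for adipocyte markers and 0.649 for the other 17.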

How the results depend on the processing

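Tests added after the data were seen were the runs without the 4 adipocyte-rich libraries and with the adipocyte marker covariate. Among results past the threshold in the main or the alternative setting, the sign changed in 2 cases, both lists in the interaction: Adipocyte markers with 1 surrogate variable (adjusted p = 0.393) and Smooth muscle and pericyte markers without the 4 adipocyte-rich libraries (0.0329); the cause was not tested. Among named genes called in neither setting, Fabp4 (-0.80) went to 0.49 without the 4 libraries and 0.02 without WT male 1, and Fmod (0.15) to -0.15 without the 4 libraries. Slc25a4 stayed between 1.4995 and 1.57 on the log2 scale and past its threshold in all 20 alternatives, and r between the sexes between 0.485 and 0.718. Counting only absolute log2 fold changes of at least 1 gave 456 genes averaged, 511 in females, 480 in males, 0 for the interaction, 178 for sex in WT and 42 for sex in Tg, since that setting drops smaller changes. The female libraries alone gave 1404 and the male libraries alone 2871. DESeq2 gave 87 for the interaction, 807 for sex in WT and 166 for sex in Tg. For the interaction, upper-quartile factors gave 0, no filter 8, 1 surrogate variable 16, the adipocyte marker covariate 15 and the run without the 4 libraries 7. Sex in Tg gave 129 with 1 surrogate variable, 150 with the covariate and 150 without the 4 libraries. Lists called fell from 17 to 6 in the averaged effect and from 19 to 1 in the interaction with an estimated correlation, and fry called 1 in the interaction, where it does not compare a list with other genes. The cause of the other differences was not tested. Leaving aside single lists and genes in the interaction, 6391 recomputed values kept their side of the threshold or stayed within their limit. Of the others, 37 moved, 50 newly passed the threshold and 89 no longer passed it. These values include the counts of called genes and of called lists for the interaction, many of which moved. For single lists and genes in the interaction, 1008 kept their side, 38 newly passed, 106 no longer passed and 2 changed sign.

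With 1 library left out, counts ranged from 3682 to 4565 averaged, 1716 to 3163 in females, 1851 to 2844 in males, 0 to 23 for the interaction, 292 to 7.3e+02 for sex in WT and 43 to 86 for sex in Tg, and lists from 15 to 21 averaged and 16 to 22 in the interaction. Libraries that moved a count over 1.5 times were WT male 2 (292) and WT male 4 (326) for sex in WT, and Tg female 1 (43), Tg female 2 (46) and Tg male 2 (45) for sex in Tg. For the interaction they were Tg male 4 (23), WT female 3 (5), WT female 2 (3), WT female 1 and WT female 4 (2 each), and Tg female 3, WT male 2, WT male 4, Tg male 1, Tg male 2 and Tg male 3 (0 each). The share of higher calls was 56.4% averaged and 50.8% with RLE, and 49.8% without the 4 libraries. Depth limits what a count of 0 in 1 library excludes, to levels above 0.101 to 0.165 CPM. At the depth and spread per gene of these libraries, with genes drawn independently, 6% of genes with a simulated 1.5-fold interaction were called.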

Other observations

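All tests of the 4 gene lists in the next paragraph were chosen after the results of all genes were seen; the tests on the neighbours of Slc25a4 and on the stress genes within Tg were written down before their result was seen, but the bound on the share of neighbours was added afterwards.

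Eif3c stood apart from the other subunits of its complex. Of 14 tested genes of eIF3 subunits, 8 were higher and 0 lower in Tg (adjusted p = 0.00223 over the added lists, and adjusted p = 0.347 with an estimated correlation). Eif3c rose by 1.72 on the log2 scale (SE 0.05) and the next, Eif3f, by 0.34 (SE 0.08), while Eif3a stood at 0.06 (adjusted p = 0.515). Among the synthetases that load tRNAs inside mitochondria, 6 of 17 were higher and 0 lower (adjusted p = 0.140); Ears2 rose by 0.69 (SE 0.07) and Vars2 by 0.39 (SE 0.07). Of 18 imprinted genes that act on growth, 6 were higher and 2 lower (adjusted p = 0.140). Igf2 rose by 1.41 (SE 0.12), Grb10, an adaptor that dampens insulin signalling, from 60.1 to 133 CPM and H19 from 312 to 624 CPM, while the amino acid carrier gene Slc38a4 fell from 171 to 77.7 CPM. Of 19 tested fat genes, 2 of which are also adipocyte markers, 0 were higher and 0 lower (adjusted p = 0.319).

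A first hypothesis was that genes near Slc25a4 rise with it, as they might if the transgene sat beside the endogenous gene and drove its neighbours. Of 19 tested genes within 1 Mb, 2 were higher and 4 lower, where 3.26 higher are expected (one-sided exact hypergeometric p = 0.862). No excess was seen. The share of 10.5% higher has an upper 95% bound (Clopper-Pearson) of 33.1%, above the 17.2% of all tested genes, so a small excess is not excluded. For this reason the bound set beforehand, a p of at least 0.05, was wrong as a test against the hypothesis.

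Another hypothesis was that the mean of the list of ATF4 and stress-response regulators may rise with Slc25a4 among the 8 Tg libraries. Pearson r was 0.515 (exact permutation p = 0.202) and Spearman rho 0.714 (exact permutation p = 0.0576, two-sided over 40320 orders), and r was 0.461 without the 2 libraries farthest from the median of Slc25a4. The rise did not pass the threshold and stays open, since 8 libraries leave wide room for chance. Females and males were exchanged together in this test, so a difference between the sexes could also make or hide a correlation. The bound set beforehand, a p of at least 0.05, was wrong here too, since a missed threshold at this number excludes nothing.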
